A study of Mus musculus with 72 samples.

How the data were processed

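Total RNA was measured by sequencing in olfactory epithelium, the sensory lining of the nose, of young mice. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded total RNA kit after removal of ribosomal RNA. The 72 libraries fall into 25 groups by genotype, postnatal day (P) and doxycycline (DOX), of which 22 hold 3 libraries and 3 hold 2. The labels do not state that the libraries of a group come from separate animals, so the p-values measure the spread between these samples. The titles of all 3 libraries of ectopicFzd1 with DOX at P3 carry the same ID, and 1 library of ectopicFzd1 with DOX at P10 shares an ID with 1 at P14. At P3 Y-linked genes were at 207.2 CPM in replicate 1 and below 1 CPM in the others, so not all 3 are 1 animal, but replicates 2 and 3 could be, and the tests with this group carry that doubt.

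Per the submitters' processing notes, the authors made reads with bcl2fastq 2.18 and aligned them to the mouse genome build mm10 with STAR 2.6.1c. The deposited count table holds whole read counts per gene from STAR, with the read totals outside genes. The deposited TPM table holds expression values from RSEM, scaled by the authors for gene length and library. The version of RSEM, the annotation release and the use of strand in counting are not stated, so antisense and overlapping genes are uncertain. Counts of odorant and vomeronasal receptor families and of processed pseudogenes are uncertain too, since near-identical copies can share or lose reads. Of the 54532 gene IDs in the count table, 54495 (99.93%) matched a GENCODE annotation of the same build, which gave the positions, and 53921 of them had the same symbol there.

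The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the groups, which left 22144, libraries were scaled by TMM, and a quasi-likelihood model with 1 term per group and the trended dispersion was fitted to all 72 libraries. Adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood test over all genes tested, with a threshold of 0.05, and a gene past it is called higher or lower. Of the 6 averaged comparisons, ectopicFzd1 against control and Fzd1lacZ against control without DOX take the mean log2 fold change over P0, P3, P7, P10 and P14. With DOX, ectopicFzd1 against control takes the mean over P1, P3, P7, P10 and P14. The DOX difference (ectopic effect without DOX minus ectopic effect with DOX) and DOX against no DOX in control take the mean over P3, P7, P10 and P14. P14 against P0 takes the mean over the 3 genotypes without DOX. A further 15 comparisons are at single ages, and 3 F tests ask whether an effect differs among ages. Errors beside log2 fold changes are standard errors (SE).

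The level of Fzd1 as log2(CPM + 1), CPM being counts scaled to the library size with its TMM factor, and the percent of gene counts in odorant receptor genes were compared by exact permutation of genotype within age, with every arrangement counted, 2-sided. The 33 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists within a comparison. Called genes per chromosome, and within 10 Mb of Fzd1 and of Omp, were compared with Fisher's exact test. Intervals on shares of counts are 95% Wilson intervals and cover counting error only.

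Genes named are Fzd1 in every comparison, the 10 largest rises and the 10 largest falls of an averaged comparison among called genes with an average log2 CPM above 0, the same direction at every age (for P14 against P0, in every genotype) and a symbol that is not a predicted or clone name, and up to 4 called members of each list that passed its test or held at least 3 called members. Single ages name up to 3 genes per direction without the condition on ages, and the tests by age and the DOX difference name 6 genes by smallest p.

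The steps were tested on simulated counts with 200 changed genes. In the averaged ectopic comparison edgeR called 44% of genes changed by 0.5 on the log2 scale and all of those changed by 1 or by 2, with 4 unchanged genes called. For the same genes in the ectopic comparison at P10 it called 0%, 40% and 100%, and in the DOX difference 10%, 78% and 100%. Of 50 genes changed at P10 alone, the test by age called 92%. The counts were simulated with a dispersion of 0.05 and the real library sizes. In the averaged comparison limma on log2 values called 42%, 98% and 100%, and DESeq2 called 54%, 100% and 100%.

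Alternatives tried were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter on a mean CPM of at least 1, a fit on only the groups compared, limma on log2 TPM with pseudocounts of 1 and 0.1, subsets of ages, the ID series in the titles as a covariate, and leaving out each library in turn. The results of 2 named genes are not reported here, and their values under the alternatives are not counted. Added after the data were seen were the share of a satellite-like gene family as a covariate, fits without libraries rich in it, fits without the libraries whose Fzd1 level goes against their label, and further subsets of ages. No paired analysis was possible because the labels give no replicate numbers. For each averaged comparison and test by age, 40 splits of the libraries into groups of the same sizes, the real one among them, were fitted the same way, and for each age with 3 libraries per group all 10 splits were. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 ran the permutations, and matplotlib 3.10.9 drew the figures.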

Results

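Gene expression was measured in olfactory epithelium of mice of 3 genotypes. Control mice carried Omp-IRES-tTA, which makes the tetracycline-controlled activator tTA in cells that express Omp, the gene of olfactory marker protein in mature olfactory sensory neurons. The ectopicFzd1 mice also carried tetO-Fzd1-IRES-tdTomato, so that tTA drives the Wnt receptor gene Fzd1 unless DOX is given. Fzd1lacZ mice carried a knockout allele of Fzd1. All 3 genotypes were sampled without DOX at P0, P3, P7, P10 and P14, and control and ectopicFzd1 mice given DOX from P0 were sampled at P1, P3, P7, P10 and P14. The knockout groups were compared with Omp-IRES-tTA mice, since the labels give no wild-type littermates. Each group held 3 libraries, except control without DOX at P3 and at P7 and ectopicFzd1 without DOX at P14, which held 2.

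Gene counts per library ranged from 1.315 M (Fzd1lacZ P10 replicate 1) to 8.788 M, with a median of 4.28 M, out of 10.48 M to 19.72 M reads. Reads assigned to genes made up 8.953% to 47.24% of all reads. A family of 12 predicted genes including Gm10800, which resemble satellite repeats, took 0.05396% to 73.72% of gene counts with a median of 7.53%. It exceeded 25% in 8 libraries, among them Fzd1lacZ P10 replicates 1 and 3. Odorant receptor genes, of which 945 to 1240 had a count per library, took 0.04896% to 0.5766% of gene counts. The library with 73.72% in the Gm10800-type family had 0.2553% in odorant receptors, with a 95% Wilson interval of 0.2483% to 0.2626% that covers counting error only. The first 3 principal components held 34.4%, 14.4% and 4.27% of the variance.

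Fzd1 (ENSMUSG00000044674, mm10 chromosome 5, 4753839 to 4758035) was examined first, since it checks the labels. In the 13 control libraries without DOX it lay between 20.94 and 44.27 CPM. In ectopicFzd1 without DOX it lay between 205 and 2122 CPM in 13 of 14 libraries, and at 42.99 CPM in the library labelled ectopicFzd1 P3 replicate 3. In the 15 Fzd1lacZ libraries it lay between 3.477 and 20.31 CPM, below the lowest control library. With DOX it lay between 20.69 and 54.33 CPM in 14 control libraries, at 3.448 CPM in the library labelled control DOX P7 replicate 1, and between 21.98 and 63.98 CPM in the 15 ectopicFzd1 libraries. The libraries labelled ectopicFzd1 P3 replicate 3 and control DOX P7 replicate 1 therefore went against their labels, and directions at these ages are drawn in part from them. By age, ectopicFzd1 without DOX had 298.8 CPM ± 81.66 (SD, n = 3) at P0 and 1882 CPM ± 338.7 (SD, n = 2) at P14, beside 40.49 CPM ± 3.3 (SD, n = 3) and 23.4 CPM ± 2.49 (SD, n = 3) in control.

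**Figure D1:**
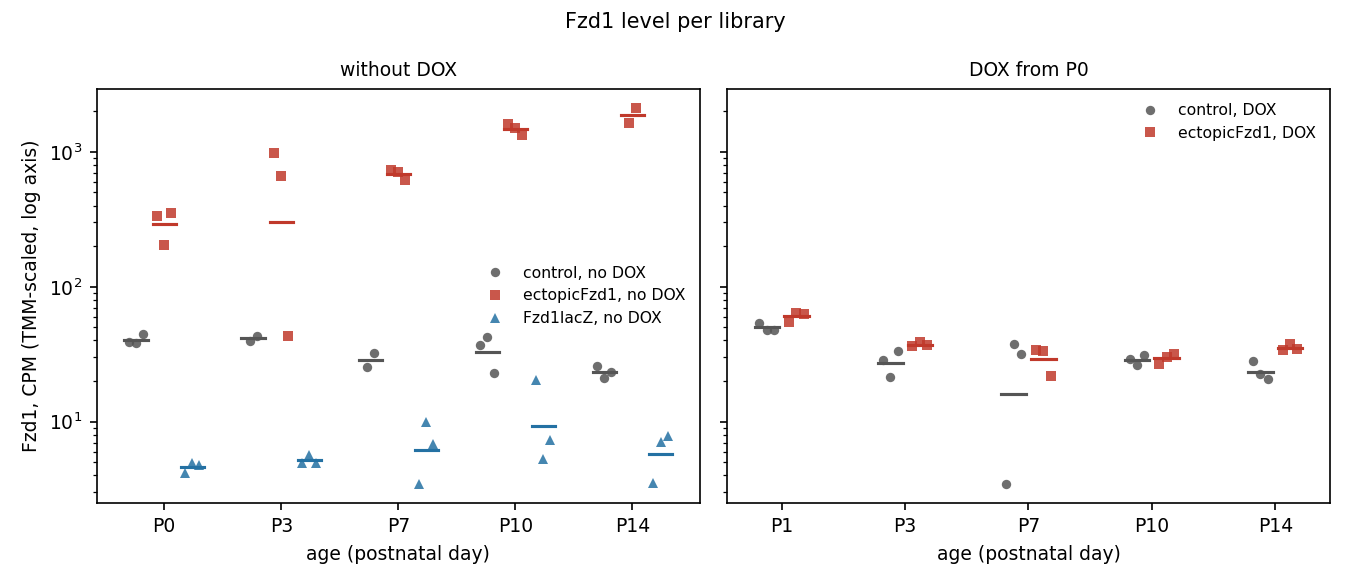
Fzd1 level per library as TMM-scaled CPM on a log axis, by genotype, DOX and age. Control libraries without DOX lay between 20.94 and 44.27, Fzd1lacZ libraries between 3.477 and 20.31, and ectopicFzd1 libraries without DOX between 205 and 2122 except 1 at 42.99.

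The comparison of ectopicFzd1 with control without DOX asked what expression of Fzd1 in mature neurons changed. The construct carries tdTomato together with Fzd1, and no group had a tetO construct without Fzd1. Effects of Fzd1 and of tdTomato are therefore not separated, here or in the DOX difference. Averaged over ages, Fzd1 rose by 4.60 (SE 0.24) on the log2 scale (adjusted p = 4.13e-23), and an exact permutation test of its level, 2-sided, gave a difference of 4.38 (p = 5e-06, smallest possible 2.5e-06). Of 22144 genes tested, edgeR called 2035, of which 591 were higher and 1444 lower. Odorant receptor genes made up 765 of the lower genes, and 671 belonged to none of the odorant, trace amine-associated and vomeronasal receptor families. The largest rises after Fzd1 were in the processed pseudogene Rps3a3 (3.08), whose reads can be shared with its parent gene, in the calreticulin family gene Calr4 (1.59), in the sugar transporter gene Slc2a6 (1.45) and in Selenbp2 (1.11). Lmo4, which encodes a LIM-domain transcriptional cofactor, rose by 0.73 (SE 0.08, adjusted p = 2.02e-10). The largest falls were in Olfr729 (−3.05), Olfr122 (−2.76), Olfr1444 (−2.69) and Olfr1347 (−2.64), with Taar7a (−2.62) among the next. The title ID series as a covariate over P0, P3, P7 and P10 gave 973 calls, and limma on log2(TPM + 1) gave 557, of which 8 were higher. At P14 the genotypes carried different series, so genotype and series are not separated at that age.

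Of 978 odorant receptor genes tested, 765 were lower, none was higher and 880 were lower when adjusted over the list alone, with a median of −1.28 (adjusted p = 2.06e-06 with an estimated correlation). Examples are Olfr536 (ENSMUSG00000052508, −2.24), Olfr969 (−2.26), Olfr1508 (−2.05) and Olfr15 (−1.60). Fitted values were below 0 for 970 of them, and medians per chromosome ranged from −1.59 to −1.01. The percent of gene counts in odorant receptors was 0.1363 in ectopicFzd1 and 0.3333 in control, lower at 5 of 5 ages (exact permutation test, 2-sided, p = 5e-06). All 7 trace amine-associated receptor genes tested, a separate class of olfactory receptors, were lower, among them Taar6 (−1.82) and Taar4 (−1.37), with an adjusted p = 1.58e-05 with an estimated correlation. The receptors are members of large families, so values of single members are uncertain where reads can be shared.

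**Figure D2:**
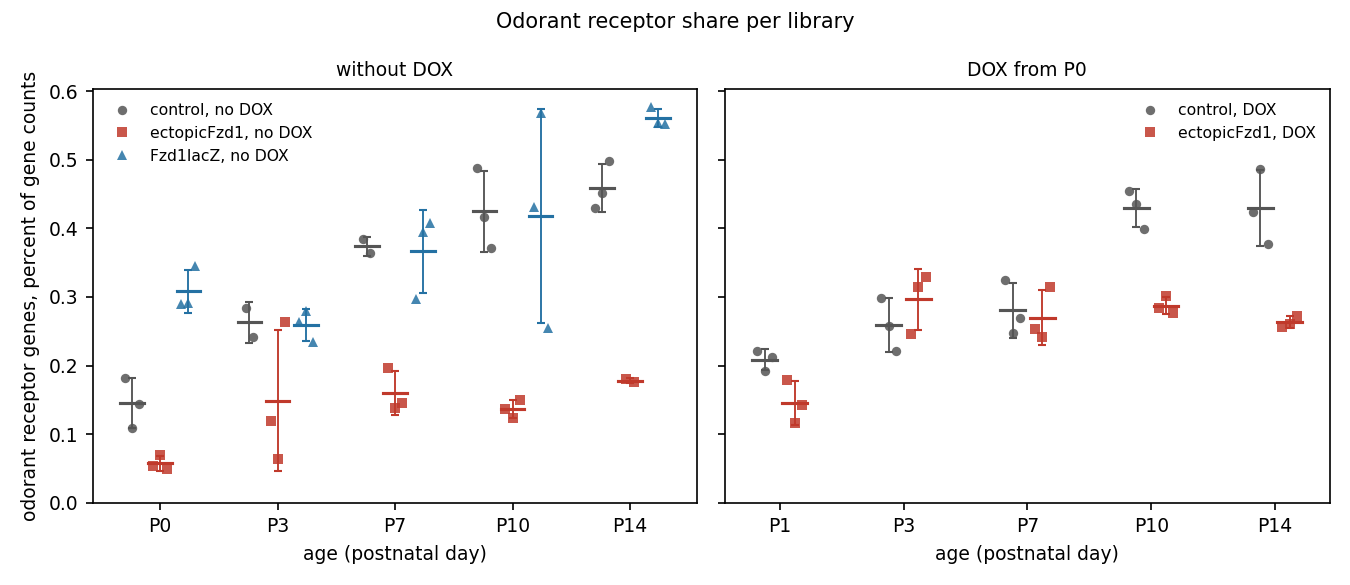
Percent of gene counts in odorant receptor genes per library, by genotype, DOX and age. Means over ages were 0.1363 in ectopicFzd1 and 0.3333 in control without DOX, and 0.2526 and 0.3215 with DOX.

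Of 19 markers of mature olfactory sensory neurons, 17 were lower (17 adjusted over the list alone), with a median of −0.70 (adjusted p = 0.0101 with an estimated correlation). Examples are Omp (ENSMUSG00000074006, chromosome 7, 98143359 to 98145502, −1.61), Stoml3 (−1.48), the phosphodiesterase gene Pde1c (−0.81) and the glutamate transporter gene Slc17a6 (−0.85). The fall in Omp was not alike among ages, with −5.57 at P14, −1.34 at P10 and no call at P0, P3 and P7. Relative to the other markers and as a percent of the Fzd1lacZ level, Omp at P14 was at 58.4 in control and 2.26 in ectopicFzd1, and at P3 at 3.45 and 3.23. Of 10 microvillar cell and ionocyte markers, 2 were higher, Foxi1 (0.30) and Hepacam2 (0.28), and 6 when adjusted over the list alone (adjusted p = 0.0471 with an estimated correlation). The next lists passed camera with the preset correlation but not with the estimated one. Of 20 cell cycle genes 9 were higher (14 adjusted over the list alone), among them Mcm6 (0.31), Top2a (0.31) and Cdk1 (0.29), with adjusted p = 0.166 with an estimated correlation. Of 13 unfolded protein and integrated stress response genes 4 were higher (6 adjusted over the list alone), namely Sdf2l1 (0.80), the chaperone gene Hspa5 (0.66), Creld2 (0.59) and Hyou1 (0.37), with adjusted p = 0.297 with an estimated correlation. Of 24 olfactory axon guidance genes 10 were lower and 1 higher (11 and 1 adjusted over the list alone), among them Kirrel2 (−1.80), Kirrel3 (−0.68) and Plxna3 (−0.61), with adjusted p = 0.428 with an estimated correlation. In the activity-dependent list, which passed camera too, S100a5 (−2.26), Lrrc3b (−0.98) and Pcp4l1 (−0.78) were lower beside Kirrel2. In the immature neuron list Gng8 (0.34) was higher, in the progenitor list Ezh2 (0.22) and in the sustentacular list Cbr2 (0.49), and the medians of these lists were positive but turned negative on the TPM scale, where the median of all genes was −0.15. Of 14 interferon response genes 2 were higher, Ifi44 (0.67) and Isg15 (0.84), and 3 when adjusted over the list alone, with adjusted p = 0.428 with an estimated correlation, while Ifit2, which is not in the list and was singled out after its values were seen, was lower (−0.34). None of 13 beta-catenin target genes, 15 planar cell polarity genes and 15 Wnt receptor and co-receptor genes, a list that leaves out Fzd1, was called by edgeR, also when adjusted over the list alone, while 4518 of all genes had an unadjusted p below 0.05.

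**Figure D3:**
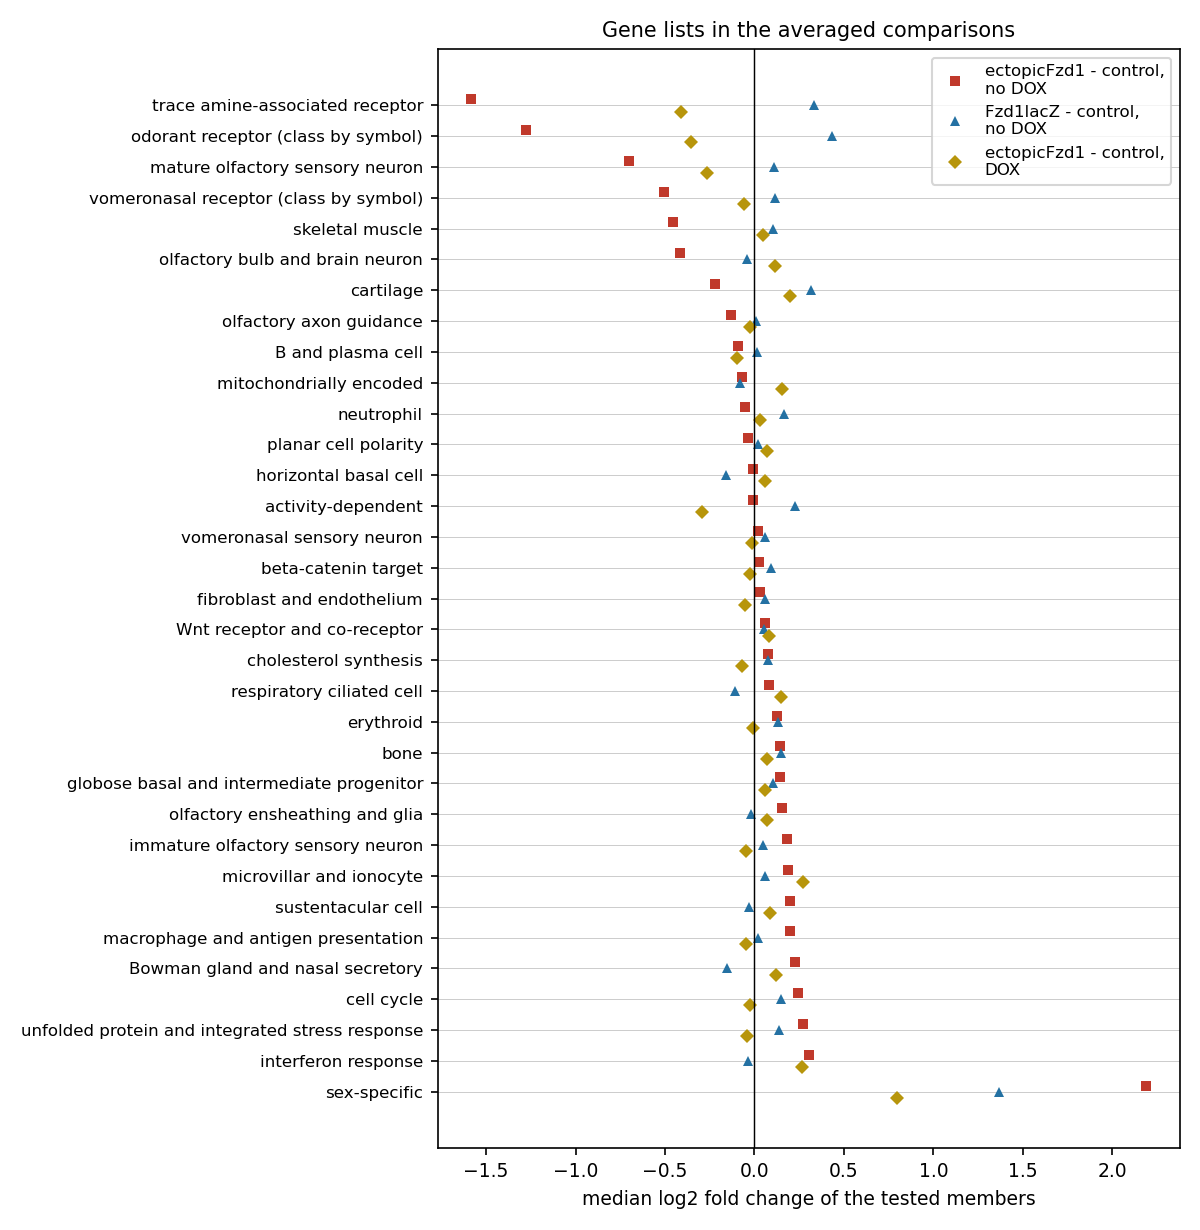
Median log2 fold change of each gene list in the averaged comparisons. In ectopicFzd1 against control without DOX the odorant receptors were at −1.28 and the mature neuron markers at −0.70, while medians of the immature neuron, progenitor and sustentacular lists were positive and turned negative on the TPM scale.

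At single ages the ectopic comparison without DOX called 167 genes at P0, 126 at P3, 156 at P7, 2289 at P10 and 389 at P14, and the median of the odorant receptors was −1.35, −0.94, −1.04, −1.71 and −1.30. Fzd1 rose by 2.88, 3.76, 4.57, 5.44 and 6.32 at these ages, drawn at P3 in part from the library labelled ectopicFzd1 P3 replicate 3. In ectopicFzd1, Omp relative to the other mature markers was at 39.9% of the Fzd1lacZ level at P0 and 2.26% to 6.02% at later ages. Age and the Omp level are therefore not separated in the growing rise of Fzd1. The P7 count fell to 1 with the title ID series as a covariate, where both control libraries were of 1 series and 2 of 3 ectopicFzd1 libraries of another. The counts depended on single libraries too. Without ectopicFzd1 P10 replicate 2 the P10 count was 547, without control P3 replicate 1 the P3 count was 4, without control P7 replicate 1 the P7 count was 12, without ectopicFzd1 P0 replicate 3 the P0 count was 60, and without ectopicFzd1 P14 replicate 2 the P14 count was 48. With the Gm10800-type share as a covariate, chosen after seeing the data, the P10 count was 1108. Among the largest changes, Hist1h2al rose by 6.01 at P0, Ptgds, which encodes prostaglandin D synthase, fell by 3.68 at P7 and rose by 4.46 at P10, and Omp fell by 5.57 at P14. The test of a difference among ages called 79 genes, with Fzd1 at adjusted p = 0.00907 and Omp at adjusted p = 9.67e-08.

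The comparison of Fzd1lacZ with control without DOX asked what loss of Fzd1 changed. Control carried Omp-IRES-tTA. Its Omp relative to the other mature neuron markers was at 2.93% to 58.4% of the Fzd1lacZ level over P0, P3, P7, P10 and P14. Genotype and this difference in Omp are therefore not separated at any age. At P0, P3, P7 and P10 the genotypes carried different ID series in the titles. Genotype and series are therefore not separated at these ages. Averaged over ages, Fzd1 fell by 2.47 (SE 0.26, adjusted p = 1.35e-10), and the exact permutation test of its level, 2-sided, gave −2.25 (p = 1.25e-06, the smallest possible). At P0 and P3 Fzd1 was called lower (−3.13 and −3.00). At P7, P10 and P14 it was not called, with −2.26, −2.16 and −1.82. Of the genes tested 630 were called, 316 higher and 314 lower, and 122 were odorant receptor genes, 1 of them lower. The count was 1950 without Fzd1lacZ P10 replicate 2, 364 without control P7 replicate 1 and 409 without control P3 replicate 2. Without the libraries above 25% in the Gm10800-type family, a setting chosen after seeing the data, it was 3191. With limma on log2(TPM + 1) it was 6388, with 60 higher and 6328 lower, where the median of all genes was −0.30. The largest rises were in BC018473 (6.59), which is annotated as antisense and so uncertain without knowledge of strand, in Trim5 (3.88), Eno1b (3.84), BC002163 (3.75) and Omp (3.40, SE 0.18, adjusted p = 2.8e-22). The largest falls were in Rprl3 (−7.01), Rprl2 (−6.11), the processed pseudogene Ftl2-ps (−4.38) and Eif3j2 (−3.81).

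Of the odorant receptor genes 121 were higher and 1 lower (305 and 5 adjusted over the list alone), with a median of 0.43 and adjusted p = 0.0732 with an estimated correlation. Among them were Olfr1507 (1.06), Olfr522 (1.01) and Olfr591 (0.91). Their percent of gene counts was 0.3827 in Fzd1lacZ and 0.3333 in control, higher at 2 of 5 ages, P0 and P14 (exact permutation test, 2-sided, p = 0.063). In 5 cases leaving out 1 library brought the p of this exact permutation test below 0.05, from p = 0.0494 without control P10 replicate 1 to p = 0.00546 without Fzd1lacZ P10 replicate 3. Outside the Gm10800-type family, a setting chosen after seeing the data, the difference was 0.163 points (exact permutation test p = 0.00419). The share was then higher at 4 of 5 ages. Leaving the family out raises the share most where the family is most abundant. Fzd1lacZ P10 replicates 1 and 3 moved from 0.431% and 0.2553% to 1.357% and 0.9717%, and replicate 2 from 0.5675% to 0.587%. By age, the median over receptors was 1.08 at P0, −0.04 at P3, 0.07 at P7, 0.60 at P10 and 0.35 at P14. At P0 the Gm10800-type share differed between the genotypes in all libraries, so the value there is not shown to follow from the knockout alone. Of 15 Bowman gland and nasal secretory genes 3 were lower (3 adjusted over the list alone), the odorant-binding protein genes Obp2b (−1.63) and Obp2a (−1.45) and the lipocalin gene Lcn3 (−1.24), with adjusted p = 0.665 with an estimated correlation. Among 10 horizontal basal cell genes, the keratin gene Krt15 (−0.93) and Trp63 (−0.39) were lower, with adjusted p = 0.935 with an estimated correlation. Cell cycle genes Plk1 (0.44), Mcm6 (0.32) and Tyms (0.28) were higher, with adjusted p = 0.935 with an estimated correlation, and the list median turned negative on the TPM scale. Cartilage genes Acan (0.46) and Col9a2 (0.44) were higher and Cnmd (−0.57) lower, with adjusted p = 0.665 with an estimated correlation, and the list median turned negative with a TPM pseudocount of 0.1. None of the lists passed with the estimated correlation. Of 19 mature neuron markers edgeR called only Omp.

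Called genes in the knockout comparison were more frequent within 10 Mb of Omp than elsewhere. Without odorant receptor genes 18 of 203 genes there were called, with an odds ratio of 4.07 (lower 95% bound 2.34, Fisher's exact test, 2-sided, p = 2.08e-06). They included the tripartite motif genes Trim12a (5.99), Trim5 (3.88), Trim34a (1.23) and Trim34b (−1.86), and the calpain gene Capn5 (−0.93) and the myosin gene Myo7a (0.85). These Trim genes and Trim12c (−0.34) lie side by side between 104244457 and 104353362, and Fisher's test counts them as independent. Omp lies within the bounds of Capn5 (98121559 to 98178274), and the use of strand in counting is not known. Capn5 is therefore not separate evidence of a change around Omp. The ectopic comparison had 12 calls among the same 203 genes (odds ratio 0.984, Fisher's exact test p = 1) and the DOX ectopic comparison 0 (p = 0.409). Within 10 Mb of Fzd1, 3 of 72 genes were called in the knockout comparison (odds ratio 1.78, Fisher's exact test p = 0.248). By whole chromosome without odorant receptors, knockout calls were more frequent on chromosomes 7 (odds ratio 1.56) and 14 (32 of 761, odds ratio 1.84). Fisher's exact test gave adjusted p = 0.0253 for each. They were less frequent on chromosome 17 (odds ratio 0.463, adjusted p = 0.0487). Ectopic calls were more frequent on chromosome 13 (odds ratio 1.7, adjusted p = 0.000425) and less on chromosome 7 (0.697, adjusted p = 0.0273).

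At single ages the knockout comparison called 1712 genes at P0, 239 at P3, 19 at P7, 63 at P10 and 158 at P14. At P0 the Gm10800-type share was 9.269% to 13.37% in Fzd1lacZ and 0.05396% to 0.6769% in control. Genotype and library make-up are therefore not separated there. With that share as a covariate, chosen after seeing the data, the counts were 283 at P0, 655 at P3 and 220 at P10. The P0 count was 252 without control P0 replicate 2, the P3 count 30 without control P3 replicate 1, the P7 count 8 without control P7 replicate 1, the P10 count 4756 without Fzd1lacZ P10 replicate 2 and the P14 count 58 without control P14 replicate 3. Omp rose by 5.15 at P7, and Trim12a by 8.26 at P3, 8.79 at P7 and 8.04 at P10, where control had no counts of it, and by 5.0, rounded to 2 digits, at P14. At P0 Trim12a was not called (−0.125), and control with DOX at P7 had it at 4.546 to 5.537 CPM. The lipocalin gene Lcn4 fell by 4.77 at P10 and fell by 6.16 at P14. The test of a difference among ages called 614 genes, among them Omp (adjusted p = 1.15e-10) and the protease gene Adamts15 (adjusted p = 4.34e-06), which fell by 1.76 at P0.

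The ectopic and knockout comparisons share their control libraries. Both called 30 genes higher, where independent lists would share 8.43, and 68 lower (20.5). Rounded to 2 digits, 1.1e+02 genes were lower in ectopicFzd1 and higher in Fzd1lacZ (20.6), and 6 were the reverse (8.38). With unchanged groups simulated against the shared controls no gene was called, which gives no reference for the shared calls, and the covariance of log2 fold changes was 0.0414, while the observed covariance across genes was −0.0151. With the controls split so that each comparison had its own, the covariance was −0.0315 and −0.0438, and both comparisons called 1 and 0 genes higher (0.718 and 0.757 if independent) and 17 and 18 lower (5.2 and 3.76). The excess of shared higher calls was therefore not seen with separate controls, where fewer genes were called, and that of shared lower calls was. Genes lower in ectopicFzd1 and higher in Fzd1lacZ numbered 56 and 16 with separate controls (6.99 and 2.7 if independent), so that excess was seen too. The reverse held for 1 and 1 (0.534 and 1.06). Genotype and the difference in Omp are not separated in the knockout comparison at any age, nor in the ectopic comparison at P14. The shared calls are therefore not shown to follow from Fzd1 alone.

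The comparison of ectopicFzd1 with control under DOX asked what remained when the transgene was switched off. At P3, P7, P10 and P14 the genotypes carried different ID series in the titles. Genotype and series are therefore not separated at these ages. Fzd1 was at 0.32 (SE 0.20, adjusted p = 0.657), and the exact permutation test of its level, 2-sided, gave 0.41 (p = 0.0069), or 0.21 (p = 0.025) without the libraries labelled against their Fzd1 level. The p rose to 0.0622 without ectopicFzd1 DOX P7 replicate 1 and to 0.0598 without replicate 2. Of the genes tested 183 were called, 69 of them lower, and 34 of the lower genes were odorant receptors. Without P3 the count was 545. The largest rises were in Rps3a3 (5.44), Hist1h2al (5.35), the pseudogene Rpl3-ps1 (3.29) and Klk1b22 (2.88). Omp fell by 3.32 (SE 0.17, adjusted p = 3.46e-23), followed by Olfr198 (−1.65) and Olfr441 (−1.23). The odorant receptors had a median of −0.35 (34 lower, 146 adjusted over the list alone, adjusted p = 0.0184 with an estimated correlation), with 0.21 at P3, where the Omp levels of the 2 genotypes were alike. Their percent of gene counts was 0.2526 in ectopicFzd1 and 0.3215 in control, lower at 4 of 5 ages (exact permutation test, 2-sided, p = 0.00229). The share was lower at 3 of 5 ages in 2 settings chosen after seeing the data, without the libraries labelled against their Fzd1 level and outside the Gm10800-type family, and at P7 the difference was −0.0103 points with overlapping ranges. At P1, P7, P10 and P14, where the share was lower with all libraries, Omp relative to the other markers was at 52.9% to 62.2% of the Fzd1lacZ level in control and 2.85% to 7.93% in ectopicFzd1, so genotype and the difference in Omp are not separated here. None of the trace amine-associated receptors was called by edgeR, at a median of −0.41 (adjusted p = 0.0184 with an estimated correlation). Microvillar and ionocyte markers Hepacam2 (0.31), Cftr (0.29) and Atp6v1b1 (0.25) were higher (8 of 10 adjusted over the list alone, adjusted p = 1.59e-05 with an estimated correlation). In the mature neuron list only Omp was called, and 11 were lower adjusted over the list alone (adjusted p = 0.0592 with an estimated correlation). Kirrel2 (−0.61) and S100a5 (−0.84) were lower, as in the comparison without DOX. Across the 978 odorant receptor genes, which are not independent replicates, the log2 fold changes with and without DOX had a Pearson correlation of 0.345 and a Spearman correlation of 0.349. Both comparisons called 19 genes higher and 53 lower, where independent lists would share 3.04 and 4.5, and only Pde4d went opposite ways. These comparisons share no libraries.

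At single ages the DOX comparison called 3282 genes at P1, 40 at P3, 126 at P7, 19 at P10 and 44 at P14. The counts were 1351 at P1 without ectopicFzd1 DOX P1 replicate 1, 6 at P3 without ectopicFzd1 DOX P3 replicate 3, 28 at P7 without ectopicFzd1 DOX P7 replicate 1, 4 at P10 without control DOX P10 replicate 2, and 1 at P14 without control DOX P14 replicate 2. The test of a difference among ages called 2126 genes, among them the transcription factor gene Nfya, which rose by 1.61 at P1, and the bone matrix gene Spp1, which fell by 3.64 at P3.

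**Figure D4:**
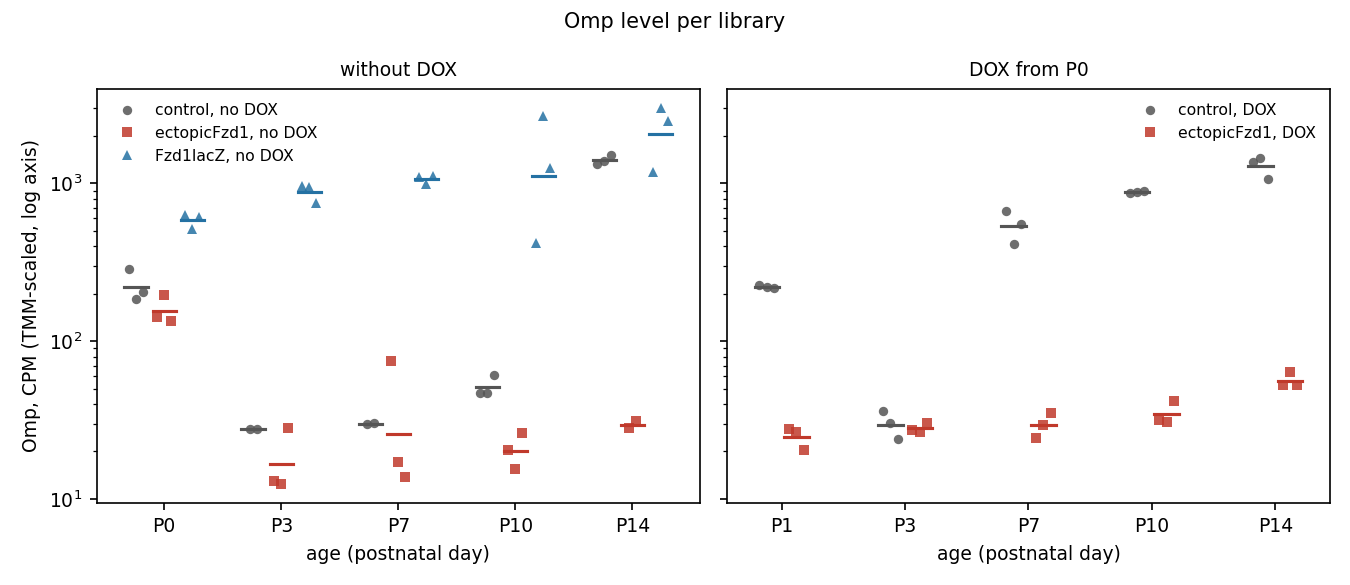
Omp level per library as TMM-scaled CPM on a log axis, by genotype, DOX and age. Fzd1lacZ libraries lay between 422.2 and 3018, and ectopicFzd1 libraries with DOX between 20.56 and 63.56. Not drawn is Omp relative to the other mature neuron markers, as a percent of the Fzd1lacZ level at a like age. Its means lay between 39.9% and 62.2% in 7 of the 20 groups with Omp-IRES-tTA, and between 2.26% and 7.93% in 13.

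The difference between the ectopic effects without and with DOX was tested directly over P3, P7, P10 and P14. At all these ages the genotypes with DOX carried different ID series in the titles, so genotype and series are not separated there. Fzd1 differed by 4.69 (SE 0.34, adjusted p = 5.38e-16). Omp differed as well (1.48, adjusted p = 0.000261, singled out after its values were seen), and at P7 and P10 relative Omp was below 10% of the Fzd1lacZ level in both genotypes without DOX but in ectopicFzd1 alone with DOX, so the called genes are not shown to follow from Fzd1 alone. Of the genes tested 530 were called, 60 higher and 470 lower, and 261 of the lower genes were odorant receptors (520 adjusted over the list alone), with a median of −0.99 (adjusted p = 0.00118 with an estimated correlation). Examples are Olfr536 (−2.03), Olfr1508 (−1.92), Olfr1346 (−2.34) and Olfr6 (−1.82), and the calcium-binding protein gene Necab1 (−1.33) was lower too. Of the trace amine-associated receptors 2 were lower (4 adjusted over the list alone, adjusted p = 0.0147 with an estimated correlation). Of the mature neuron markers 7 were lower and 1 higher (15 and 1 adjusted over the list alone, adjusted p = 0.145 with an estimated correlation). Of the stress response genes 5 were higher (7 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation).

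DOX against no DOX in control asked what differed with the drug. At P3, P7 and P10 the libraries with and without DOX carried different ID series in the titles. DOX and series are therefore not separated at these ages. Omp differed as well (2.07, adjusted p = 5.3e-11, singled out after its values were seen). Relative to the other markers it was at 52.9% and 62.2% of the Fzd1lacZ level with DOX at P7 and P10, and at 2.93% and 4.04% without, so the called genes are not shown to follow from DOX alone. Fzd1 was at −0.27 (adjusted p = 0.66) and was not called. Of the genes tested 192 were called, 128 higher and 64 lower. The balance turned in other settings, with 110 of 249 calls higher with no filter and, in settings chosen after seeing the data, 78 of 176 with the Gm10800-type covariate and 53 of 185 at P3 and P14 alone, where Omp was alike with and without DOX. Leaving out 1 library lowered the count to 49 without control P7 replicate 2, to 60 without control P3 replicate 2 and to 90 without the library labelled control DOX P7 replicate 1. The largest rises were in the chitinase-like gene Chil4 (3.44), Edn2 (1.43), the immediate-early gene Egr1 (1.22) and the calcium-binding gene S100a8 (1.04), and falls included Hebp1 (−0.82) and Mnd1 (−0.77). In the activity-dependent list 4 genes were higher (5 adjusted over the list alone, adjusted p = 0.189 with an estimated correlation), Fos (1.67), Egr1, Nr4a1 (0.91) and Btg2 (0.65). Of the odorant receptors edgeR called none, at a median of −0.19 that turned to 0.00 with a TPM pseudocount of 0.1. Among all genes 2950 had an unadjusted p below 0.05.

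P14 against P0 without DOX, averaged over the 3 genotypes, asked how the tissue changed as it matured. In each genotype P0 and P14 carried different ID series in the titles, so age and series are not separated. In control the Gm10800-type share was 0.05396% to 0.6769% at P0 and 7.353% to 15.17% at P14. In ectopicFzd1 it was 0.1163% to 0.4369% and 13.17% to 20.56%, while in Fzd1lacZ the ranges overlapped. Age and library make-up are therefore not separated in control and ectopicFzd1. With this share as a covariate, chosen after seeing the data, more genes were lower than higher. Fzd1 rose by 0.80 (adjusted p = 0.019) as an average that includes the ectopicFzd1 groups, while control had 40.49 CPM at P0 and 23.4 CPM at P14. In ectopicFzd1, Omp relative to the other mature markers was at 39.9% of the Fzd1lacZ level at P0 and 2.26% at P14. Age and this difference in Omp are not separated in that genotype. Of the genes tested 13030 were called, 6996 higher and 6034 lower, and with limma on log2(TPM + 1) 460 were higher and 10428 lower, where the median of all genes was −0.62. The largest rises were in Lcn4 (8.94), Obp1b (8.0, rounded to 2 digits), Chil4 (7.83), Moxd2 (6.81), Obp2b (6.34), Obp1a (6.09) and the bone gene Bglap (5.17). Falls were largest in Apol10c-ps (−6.04), Bpifb5 (−5.96) and the angiotensin receptor gene Agtr2 (−5.68). Of the odorant receptors 840 were higher and 1 lower (853 and 1 adjusted over the list alone, adjusted p = 0.0764 with an estimated correlation), and of 19 mature neuron markers 18 were higher and 1 lower (adjusted p = 0.121 with an estimated correlation). Of 20 cell cycle genes 19 were lower (adjusted p = 0.104 with an estimated correlation), as were all 10 horizontal basal cell genes (adjusted p = 0.121 with an estimated correlation) and 11 of 15 Wnt receptor genes (adjusted p = 0.121 with an estimated correlation). Of 11 bone genes 10 were higher (adjusted p = 0.0764 with an estimated correlation). Of 17 immature neuron genes 13 were higher (adjusted p = 0.423 with an estimated correlation) and a median that turned negative on the TPM scale.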

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

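The tests of the 3 patterns below were chosen after the results were seen, while the tests of a difference between DOX states and among ages were chosen before.

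The ectopic effect differed between DOX states for 530 genes, among them Fzd1 (edgeR adjusted p = 5.38e-16), Olfr536 (4.75e-10), Necab1 (8.31e-09), Olfr1508 (8.31e-09), Olfr1346 (8.48e-08) and Olfr6 (2.69e-07). Among ages the ectopic effect differed for 79 genes, among them Omp (9.67e-08), Ptgds (2.63e-05), Rpl26 (0.00184), Hist1h1c, Tnn and Hist1h2ac (each 0.00648) and Fzd1 (0.00907). The knockout effect differed among ages for 614 genes, among them Omp (1.15e-10), Trim12a (3.11e-06), Adamts15 (4.34e-06), Cep83os (8.28e-06), Fut10 (5.96e-05) and Rps13-ps1 (8.69e-05). With DOX the ectopic effect differed among ages for 2126 genes, among them Zmynd8 and Nfya (each 2.16e-08), Omp (2.57e-08), Spp1 (1.37e-06), Spice1 (4.61e-06) and Ttll10 (4.66e-06).

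Of 40 splits of the libraries, 1, the real one, gave as many calls in each of the 6 averaged comparisons. The same held for the test by age with DOX. This argues against chance at that number of splits but does not exclude it. Splits that mix groups with real differences have a wider spread and can call fewer genes. The real count and the highest other were 2035 and 128 for ectopic, 630 and 14 for knockout, 183 and 5 for ectopic with DOX, 530 and 2 for the DOX difference, 192 and 13 for DOX in control, 13030 and 5150 for age, and 2126 and 930 for the test by age with DOX. The splits did not argue against chance for the test by age of the ectopic effect. There 5 of 40 splits gave at least its 79 calls and the highest other gave 223. Nor did they for the test by age of the knockout effect, where 4 of 40 gave at least 614 and the highest other gave 3054.

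At single ages with 3 libraries per group 10 splits are too few for a share under 0.05. The real count and the highest other were 167 and 5 for ectopic P0, 2289 and 1 for ectopic P10, 1712 and 6 for knockout P0, 158 and 6 for knockout P14, 3282 and 672 for ectopic with DOX P1, 40 and 2 for P3, 126 and 26 for P7, 19 and 0 for P10, and 44 and 0 for P14. For knockout P10 they were 63 and 4248, with 3 of 10 splits at 63 or more. The split with 4248 calls put control P10 replicate 3 with Fzd1lacZ P10 replicates 1 and 3, the 3 libraries of that age above 25% in the Gm10800-type family, and points to a structure of the samples.

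The first pattern is that Omp differed between groups far more than the other markers of mature olfactory neurons, by −3.32 between genotypes with DOX. A different number of mature neurons as the whole cause is argued against by the other markers, whose median was −0.24 (SD 0.171). Different numbers of copies of the Omp-IRES-tTA allele, which would replace Omp, could be the source: of 20 groups with the allele 0 lay outside the ranges of 2.26% to 7.93% and 39.9% to 62.2% of the knockout level. Those ranges were drawn from the values themselves, so the test cannot decide, and the labels do not give the number of copies. Whatever its source, this difference in Omp level goes with the groups compared, and there genotype or DOX and the difference in Omp cannot be told apart. This holds for ectopicFzd1 against control with DOX at P1, P7, P10 and P14 and so for the DOX difference at P7 and P10, for control with and without DOX at P7 and P10, for ectopicFzd1 against control without DOX at P14, and for Fzd1lacZ against control at all ages. In ectopicFzd1 without DOX relative Omp was at 39.9% at P0 and at 2.26% at P14, so age and Omp are not separated there. The tests among ages carry the same limit, since the difference in Omp between genotypes changed with age.

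The second pattern is that odorant receptors fell more (median −1.28) than the other markers of mature neurons (median −0.677, SD 0.354) in the averaged ectopic comparison. Fewer mature neurons with unchanged transcripts as the whole cause is argued against, as far as the markers are confined to those neurons, by the level of the receptors minus that of the markers. It differed by −0.285 (permutation p = 0.00606) and was lower at 4 of 5 ages. The pattern was picked from these same libraries, so this p is not independent support. The knockout against the same controls differed by 0.332 (permutation p = 0.0167), and ectopicFzd1 against control with DOX by −0.0484 (permutation p = 0.599). Gm10800-type reads are argued against by a median of −1.24 with their share as a covariate, beside −1.28 without. For later maturation of the whole tissue, the first bound used, on observed minus predicted values of 41 non-neuronal genes that rose with age (median 1.42, SD 1.65), left the question open. A second bound, set after that outcome was known because the first SD also held the spread of the age changes, went against it. The observed median was 0.198 (SD 0.313) where −1.24 was predicted, and 41 of 41 genes lay above their prediction. The prediction gave every gene the receptors' fraction of the age change, −0.827. The genes were chosen by a rise with age that includes the ectopicFzd1 libraries. With the 2 bounds in disagreement, the test cannot decide on later maturation of the whole tissue. An effect of the transgene on receptor expression within neurons remains open as a hypothesis, with Fzd1 and tdTomato not separated. For neuron number this hypothesis rests on the markers being confined to mature neurons. Later maturation of the whole tissue remains open beside it. Later maturation of the neurons alone was not tested, since the 41 genes are non-neuronal, and remains open too.

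The third pattern is that genes called in the averaged knockout comparison gathered around Omp on chromosome 7. An excess of calls was not confined to this region. Chromosome 14 had one too (odds ratio 1.84 without odorant receptors, Fisher's exact test adjusted p = 0.0253). A different number of mature neurons as the whole cause is argued against by the other markers of these neurons, whose median was 0.106 (SD 0.185). The 18 called genes near Omp that are not odorant receptors had a median size of change of 0.783. Called genes have large changes by selection, so that size adds nothing to the argument. Gm10800-type reads are argued against by an odds ratio of 3.28 (lower 95% bound 1.92) with their share as a covariate. A strain difference around the modified Omp locus could be the source, but the test could not decide. Of the genes near Omp 55.6% had the same direction at all 5 ages, beside 60.5% of called genes elsewhere. The test presumed that control groups of all ages were alike in this region, and Trim12a went against that. Control libraries had it at 4.096 to 15.62 CPM at P0 without DOX and 4.546 to 5.537 CPM at P7 with DOX. All other control libraries had at most 0.3377 CPM. A regional effect of the modified allele remains open too and was not tested.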

How the results depend on the processing

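The covariate of the Gm10800-type share, the fits without libraries above 25% of it, the fits without the 2 libraries against their labels, and the fits without P14, at P3 alone and at P3 and P14 alone were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers. Single ages hold fewer libraries than the averages and detect less: at P10 the simulated ectopic comparison called 40% of genes changed by 1 on the log2 scale, where the average over ages called all. The balance of higher and lower calls turned to 11 and 29 in ectopic with DOX average at P3 alone and to 5231 and 5831 in age with the Gm10800-type covariate. A count is given here where it moved by more than 1.5 times from that reported, and the cause was not tested unless stated. Counts written with an exponent are rounded to 2 digits. With a mean CPM of at least 1, all 24 counts stayed within that factor.

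Fitted on only the groups compared, which leaves fewer libraries to estimate the spread, the counts were 385 in ectopic with DOX average, 844 in DOX difference, 1377 in DOX in control, 12 in ectopic P0, 0 in ectopic P3, 243 in ectopic P7, 1562 in ectopic P14, 1551 in knockout P3, 12 in knockout P10, 98 in knockout P14, 730 in ectopic with DOX P1, 28 in ectopic with DOX P7, 475 in ectopic with DOX P10, 331 in ectopic with DOX P14, 185 in ectopic by age, 193 in knockout by age and 3219 in ectopic with DOX by age. The DESeq2 Wald test gave 487 in DOX in control, 513 in knockout P3, 128 in knockout P10, 75 in ectopic with DOX P3, 223 in ectopic with DOX P7, 48 in ectopic with DOX P10 and 85 in ectopic with DOX P14. The DESeq2 likelihood ratio test gave 278 in ectopic by age and 1424 in knockout by age. With no filter, and so 50892 genes tested, the counts were 204 in ectopic P3, 248 in ectopic P7, 2771 in knockout P0, 414 in knockout P3, 137 in knockout P7, 202 in knockout P10, 250 in knockout P14, 1597 in ectopic with DOX P1, 151 in ectopic with DOX P3, 590 in ectopic with DOX P7, 200 in ectopic with DOX P10, 172 in ectopic with DOX P14, 420 in ectopic by age and 2240 in knockout by age. With DESeq2 size factors edgeR called 333 in DOX in control, 395 in knockout P3 and 1.4e+02 in ectopic by age.

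With the Gm10800-type covariate the counts were 288 in ectopic with DOX average, 1108 in ectopic P10, 283 in knockout P0, 655 in knockout P3, 220 in knockout P10, 288 in knockout by age and 3387 in ectopic with DOX by age. Without the libraries above 25% they were 3191 in knockout average, 436 in ectopic with DOX average, 484 in DOX in control, 330 in ectopic P7, 362 in knockout P7, 1239 in knockout P10, 506 in knockout P14, 153 in ectopic with DOX P14, 227 in ectopic by age, 7392 in knockout by age and 4427 in ectopic with DOX by age. Without the 2 libraries against their labels they were 110 in DOX in control and 306 in ectopic P3. With the title ID series as a covariate over 4 ages the count was 973 in ectopic average. At single ages with that covariate it was 1 in ectopic P7. At P0, P3 and P10 alone it was 1126 in ectopic average. Without P3 it was 545 in ectopic with DOX average. Without P7 it was 289 in ectopic with DOX average. At P3 alone it was 40 in ectopic with DOX average. At P14 alone it was 158 in knockout average.

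With limma on log2(TPM + 1) and a mean TPM of at least 1 the counts were 557 in ectopic average (8 higher), 6388 in knockout average (60 higher), 31 in ectopic with DOX average (24 higher), 81 in DOX difference (2 higher) and 27 in DOX in control (19 higher). With a pseudocount of 0.1 they were 486 in ectopic average (5 higher), 7458 in knockout average (55 higher), 25 in ectopic with DOX average (19 higher), 95 in DOX difference (1 higher) and 20 in DOX in control (11 higher). With all genes above 0 TPM they were 1228 in ectopic average (8 higher), 2624 in knockout average (99 higher), 41 in ectopic with DOX average (26 higher), 1.2e+02 in DOX difference (2 higher) and 39 in DOX in control (12 higher). As reported, 591 of 2035 ectopic, 316 of 630 knockout, 69 lower of 183 ectopic with DOX, 60 of 530 DOX difference and 128 of 192 DOX in control calls stand beside these, with numbers higher unless stated. The age counts stayed within 1.5 times of 13030, but 460, 454 and 919 genes were higher under these 3 settings, beside 6996. On this scale the median of all genes with a mean TPM of at least 1 moved to −0.15 in the ectopic, −0.30 in the knockout and −0.62 in the age comparison, so more genes fell than rose. The TPM scale left the Fzd1 level on the same side of 0.05 in all 4 comparisons. With an estimated correlation the number of gene lists past 0.05 was 4 in ectopic average, 0 in knockout average, 3 in ectopic with DOX average, 2 in DOX difference, 0 in DOX in control and 0 in age. The share outside the Gm10800-type family was a setting chosen after seeing the data. With it the difference in odorant receptor share passed 0.05 in the knockout comparison (0.163 points, permutation p = 0.00419) and in DOX in control (−0.0597 points, permutation p = 0.037).

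Of 11759 values of named genes under the alternatives, 10607 kept their direction and their side of the threshold, 1086 kept only the direction, 6 crossed the threshold upward and 60 changed sign. With the Gm10800-type covariate the sign changed in age Slc4a1 (−0.1), Hbb-bt (0.049), Epb42 (−1.14), Myh1 (−0.029), Ryr1 (−0.591), Myh4 (−0.659), Slc17a7 (−0.453), mt-Nd6 (−0.645), Vmn2r4 (−0.041), Vmn2r6 (−0.436) and Vmn2r3 (−0.276). Without the 2 libraries against their labels the sign changed in ectopic with DOX P7 Fzd1 (−0.217). At P3 alone the sign changed in ectopic with DOX average Cftr (−0.043), Cfap43 (−0.302), Ifi44 (−0.045), Olfr1442 (0.065) and Olfr31 (0.469). At P14 alone the sign changed in knockout average Col9a2 (−0.009). With limma on log2(TPM + 1) the sign changed in ectopic average Ezh2 (−0.01) and Gnai2 (−0.038), and in knockout average Mcm6 (−0.085), Plk1 (−0.047) and Tyms (−0.077), and in age Sox2 (−0.312), Sox11 (−0.217), Gnao1 (−0.141), Bcl11b (−0.296), mt-Nd2 (−0.309), mt-Nd4 (−0.391), mt-Nd1 (−0.442) and Taar7d (−0.011). With a TPM pseudocount of 0.1 the sign changed in ectopic average Ezh2 (−0.01) and Gnai2 (−0.04), and in knockout average Mcm6 (−0.14), Plk1 (−0.113) and Tyms (−0.141), and in age Sox2 (−0.337), Sox11 (−0.234), Gnao1 (−0.151), Bcl11b (−0.352), mt-Nd2 (−0.312), mt-Nd4 (−0.393) and mt-Nd1 (−0.443). With all genes above 0 TPM the sign changed in ectopic average Ezh2 (−0.01) and Gnai2 (−0.038), and in knockout average Mcm6 (−0.085), Plk1 (−0.047) and Tyms (−0.077), and in age Sox2 (−0.312), Sox11 (−0.217), Slc4a1 (−0.28), Gnao1 (−0.141), Bcl11b (−0.296), mt-Nd2 (−0.309), mt-Nd4 (−0.391), mt-Nd1 (−0.442) and Taar7d (−0.011). Leaving out 1 library turned Fzd1 with DOX, at P7 to −0.217 without the library labelled control_DOX_P7 replicate 1, and at P10 to −0.006 without ectopicFzd1_DOX_P10 replicate 3 and −0.011 without control_DOX_P10 replicate 2, within ranges up to 0.751 at P7 and 0.112 at P10.

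Leaving out each library in turn gave ranges of counts and values, with the lone sample assumed to vary like the other groups where it left an arm with 1 sample. Counts ranged from 124 to 215 in ectopic with DOX average, 369 to 716 in DOX difference, 1 to 65 in ectopic with DOX P14, 1157 to 2784 in ectopic with DOX by age, 4 to 26 in ectopic with DOX P10, 28 to 178 in ectopic with DOX P7, 1351 to 4215 in ectopic with DOX P1, 6 to 29 in ectopic with DOX P3 and 49 to 186 in DOX in control. Further counts ranged from 1399 to 2251 in ectopic average, 364 to 1950 in knockout average, 547 to 2092 in ectopic P10, 20 to 4756 in knockout P10, 29 to 238 in ectopic by age, 136 to 5433 in knockout by age, 12 to 151 in ectopic P7, 8 to 16 in knockout P7 and 11985 to 12901 in age. The remaining counts ranged from 60 to 198 in ectopic P0, 252 to 1192 in knockout P0, 4 to 455 in ectopic P3, 30 to 112 in knockout P3, 48 to 299 in ectopic P14 and 58 to 167 in knockout P14. The Fzd1 level ranged from 4.21 to 4.66 in ectopic, −2.35 to −2.17 in knockout, 0.213 to 0.525 in ectopic with DOX and −0.516 to −0.126 in DOX in control. The difference in odorant receptor share, in points, ranged from −0.208 to −0.189 in ectopic, 0.0344 to 0.0656 in knockout, −0.0741 to −0.0631 in ectopic with DOX and −0.0379 to −0.0228 in DOX in control. The count of 1950 in the knockout average came without Fzd1lacZ P10 replicate 2, which left the pair of libraries of that group with the highest Gm10800-type shares.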

Other observations

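The histone genes and their counts were chosen after their values were seen.

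Histone genes were in no fixed list. Of 59 genes with a symbol starting with Hist, 44 were higher and 0 lower in the averaged ectopic comparison without DOX (edgeR), with a median of 0.48. By age the median was −0.21 at P0, 0.19 at P3, 0.76 at P7, 1.07 at P10 and 0.58 at P14, and at single ages 44 were called higher at P10 and at most 1 at each other age. At P10 reads assigned to genes were 17.16% to 23.06% in control and 25.87% to 40.14% in ectopicFzd1. With the Gm10800-type share as a covariate the P10 count over all genes was 1108, beside 2289 without. The knockout comparison, which shares these controls, had medians of 0.72 at P7 and 0.63 at P10 with 1 gene higher at each. In the DOX difference 16 were higher, with a median of 0.61. In the knockout at P0 29 were lower (median −0.81), and with DOX at P1 35 were lower (median −0.79). In the P0 libraries reads assigned to genes were 24.01% to 26.73% in Fzd1lacZ and 38.1% to 46.81% in control. The Gm10800-type share differed between these libraries too. Most histone transcripts lack a poly(A) tail and are measured by total RNA sequencing, and no explanation of their change was tested.

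The sex-specific list (Xist and Y-linked genes) had a median of 2.19 in the averaged ectopic comparison with no member called by edgeR, and sex was not balanced between the groups. The 5 control libraries at P7 and P10 without DOX had Y-linked genes at 0.895 to 3.801 CPM, beside 219.6 and 250.1 CPM in ectopicFzd1 P7 replicates 1 and 3 and 258.9 CPM in ectopicFzd1 P10 replicate 2. Some libraries held both kinds of transcript, such as ectopicFzd1 P10 replicate 1 with Xist at 720.6 and Y-linked genes at 66.89 CPM. No fit with sex was made.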
